A study of Caenorhabditis elegans with 2 samples.

How the data were processed

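ChIP-seq of GFP-tagged EGL-44 with an anti-GFP antibody was done on whole young adult worms grown for 66.5 h, in 2 biological replicates, with chromatin sheared by sonication to 200 to 800 (size range, per the labels). Per the labels, the tag was inserted at egl-44 by CRISPR. The 8 peak files hold, for each replicate and for both together, a ranked list of called regions and a list limited by a reproducibility threshold, and for both together also a conservative list. The aligner, the peak caller and their versions are not given in the sources used here, and the control library was not used here. Each region carries a signal value as the authors deposited it; its scaling between libraries is not stated, so signals were used only to rank and describe regions within a list. The ranked lists carry the deposited −log10 of the global irreproducible discovery rate (IDR). In the tested files every thresholded list equalled the ranked regions with a global IDR of 0.01 or less, minus a few regions (23 for the pooled list, 25 for the conservative, 15 for replicate 1 and 18 for replicate 2).

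The pooled ranked list held 79828 regions, of which 1553 were in the pooled thresholded list and 78252 were above the IDR limit. The latter served as controls and are called weaker or sub-threshold regions. The conservative list came from a ranked list of 76689 regions that gives the signals of the 2 inputs compared; these columns carry no replicate name, so none was assigned. A further 6 such input columns of the other ranked lists were not used. No file used here gives read counts, so depth is unknown, and intervals cover the counting of regions or genes only. Regions and genes are not independent replicates: 100 pooled peaks overlapped their neighbour, and p-values across regions or genes describe these lists, not the spread between worms.

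Chromosome names and lengths of assembly ce11 were checked against the reference genome, and every region lay within it. Transcript starts came from Ensembl release 115, and symbols from RefSeq, which matched 46881 of 46926 genes. A promoter peak has its summit 1000 bp upstream to 200 bp downstream of an annotated transcript start. Location classes were assigned in the order promoter window, coding exon, 5' UTR, 3' UTR, intron and intergenic. Shares were compared by Fisher's exact test, two-sided, with the sample odds ratio and exact conditional 95% bounds, and shares carry 95% Wilson intervals. Replicate overlap was set against 1000 random draws from the other replicate's ranked list. Differences in median signal and the trend of the word over signal quintiles used 100000 permutations. Each gene list was compared with all other nuclear genes of the same biotypes, with Benjamini-Hochberg adjustment over the 21 lists and calls at an adjusted p under 0.05; 2 list symbols had no match. The word CATTCC or its reverse complement was sought within 100 bp of each summit, with 5 controls per peak matched on promoter status and GC decile. The matched controls had a mean GC content of 45.4% and the peaks 45.6%, against 40.0% in all weaker regions.

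The named genes follow a rule fixed before the data were examined: the 20 peaks of highest signal named by the nearest protein-coding start within 2000 bp, up to 4 members per list with the strongest promoter peak, and 11 genes tied to EGL-44 (egl-44, egl-46, yap-1, mec-3, mec-4, mec-7, mec-17, mec-18, cye-1, unc-86 and zag-1). The small non-coding RNA genes named at the strongest peaks, and the test of that class, were chosen after the peaks had been seen. Alternatives covered the overlap rule, the list used, each replicate's own list, the IDR limit, promoter windows, the gene background, the arm length, word windows, a longer word and unmatched controls.

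The tests were tested on simulated data. With 10 of 40 members given a peak, 100 of 100 simulated gene lists were called enriched, and 2 of 100 random lists were. With the word added to 10% of simulated peaks, 100 of 100 sets of 1553 were called, and 3 of 100 without it. The simulated peaks were drawn from the same weaker regions as their controls. The rate without the word therefore does not cover other sequence differences between real peaks and weaker regions. Smaller excesses were not simulated. The overlap code recovered 307 of 307 planted regions. These were unchanged copies of replicate 1's own peaks, so this checks the code only and not the random draws or their p. Shuffled signals passed the signal test in 2 of 40 runs and signals raised by 20% at promoters in 40 of 40; the word trend passed in 0 of 40 flat runs and 40 of 40 rising ones. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.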

Results

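Chromatin bound by EGL-44, the TEA domain (TEAD) protein of Caenorhabditis elegans, was mapped by ChIP-seq with an anti-GFP antibody in whole young adult worms aged 66.5 h. EGL-44 acts with the zinc finger protein EGL-46 to block touch receptor fate in other neurons, and TEAD proteins are the DNA-binding partners of the YAP coactivator in the Hippo pathway. The worms carried GFP inserted at egl-44 itself, so the antibody was directed at the tagged EGL-44 protein. A single group of 2 biological replicates was profiled, with no other stage, genotype or treatment, so the comparisons are between the replicates, between peaks and weaker regions, and between gene groups. The pooled peak list held 1553 regions, a conservative list held 1442, and the lists of replicate 1 and replicate 2 held 769 and 568. Read counts were not used here, so the sequencing depth behind each region is unknown and no depth-based interval is given for a signal value. Coordinates are on assembly ce11.

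The strongest nuclear peaks lay at genes for small non-coding RNAs and at ribosomal protein promoters. The highest nuclear signal, 491.97, was at V:8500424-8500681, with its summit 31 bp from the start of the snoRNA gene ZK994.7 and inside an intron. The snoRNA genes C51F7.4 (signal 443.7), T03F7.8 (389.6) and W03C9.9 (363.57) followed. The promoter of rpl-3, a ribosomal protein gene of the large subunit, held a peak of signal 362.2 at III:3867480-3867662, and tasp-1 held a peak of 336.6 with the summit 25 bp upstream of its start. The peak of signal 302.5 at III:7854604-7854766 was 451 bp upstream of rpl-35, and a peak of 291.95 lay 18 bp from the start of rpr-1, the RNA of RNase P. The region IV:4727983-4728138 (292.1) was intergenic, with no protein-coding start within 2000 bp. Of the 20 strongest peaks, 9 were nuclear, and all 9 were also in both replicates' own lists. In the list that compared the 2 replicates, the values in the 2 inputs were 189.8 and 297.8 at ZK994.7, and 166.2 and 203.2 at rpl-3.

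The other 11 of the 20 strongest peaks were on the mitochondrial genome. The highest, at 4609-4876 with signal 4118, was in the gene for cytochrome b, CYTB, and the next, at 12336-12616 with signal 2789, was in ND5. Peaks in COX1 (1554), COX3 (673.04) and COX2 (581.6) also ranked above every nuclear peak. The pooled list held 16 mitochondrial regions and replicate 2's list held 19, while replicate 1's list and the conservative list held 0. The ranked list of replicate 1 and the ranked list behind the conservative one also held 0. The mitochondrial regions were thus listed in 1 replicate only, at any rank. Whether their signal reflects EGL-44 binding was not tested.

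The replicates shared part of their peaks, and nearly all peaks of either were at least ranked in the other. Of replicate 1's peaks, 353 of 769 (45.9%, 95% Wilson interval 42.4 to 49.4) overlapped a replicate 2 peak by at least 1 bp. Of replicate 2's peaks, 342 of 568 (60.2%, 56.1 to 64.2) overlapped a replicate 1 peak. Random draws of as many regions from the other replicate's ranked list gave a mean of 1.47% and 1.53%, and none of 1000 draws reached the observed share (the one-sided p of these draws was 0.001 in each direction, the smallest they can give). The ranked list of replicate 2 held 96.9% of replicate 1's peaks, and that of replicate 1 held 96.9% of replicate 2's nuclear peaks. These ranked lists are long: of all ranked regions, 46.1% of replicate 1's and 55.3% of replicate 2's overlapped the other ranked list. Across the 1467 regions past the reproducibility threshold, the signals of the 2 inputs had a Spearman rho of 0.444 and a Pearson r of 0.644 on log2 values. Across the 75222 weaker regions rho was 0.23. These correlations are across regions, which are not independent replicates, and the threshold itself selects regions that rank alike. The conservative list overlapped 1230 of the 1553 pooled peaks (79.2%, 77.1 to 81.1). Both replicates' own lists held 356 of the pooled peaks, 551 were in the list of 1 replicate, and 646 were in neither.

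The question of where EGL-44 peaks lie relative to genes was addressed against the 78252 regions that the same calling ranked but left below the threshold. Promoter windows of protein-coding genes held 699 of 1553 peaks (45.01%, 42.6 to 47.5) and 27.6% of weaker regions (odds ratio 2.15, 95% interval 1.94 to 2.38, Fisher's exact test, two-sided, p = 2e-47). Coding exons held 6.89% of peaks and 26.5% of weaker regions (odds ratio 0.205, 0.167 to 0.249). Introns held 19.4% against 23.8% (odds ratio 0.77, 0.676 to 0.875), and intergenic sequence held 26.3% against 19.4% (1.49, 1.32 to 1.67). The 3' UTR share, 2.0% against 2.38%, did not differ past the threshold (Fisher adjusted p = 0.478 over the 6 classes).

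Genes for tRNAs, snoRNAs and snRNAs lay at far more peaks than weaker regions, with a smaller excess at microRNA genes and at genes annotated as ncRNA. A tRNA gene start lay within 300 bp of 252 peaks (16.23%) and of 0.392% of weaker regions (odds ratio 49.2, 41.1 to 58.8). The corresponding shares were 5.22% against 0.272% for snoRNA genes, which guide RNA modification (odds ratio 20.2, 15.3 to 26.3), and 2.19% against 0.102% for snRNA genes, the RNAs of the spliceosome (21.9, 14.1 to 33.2). For microRNA genes the odds ratio was 4.04 (1.97 to 7.47), and for genes annotated as ncRNA, at 358 peaks, it was 5.90 (5.21 to 6.68). The classes are not exclusive, and the ncRNA share was not counted without peaks of the other classes. Its excess may therefore partly recount them. For piRNA genes the shares were 1.48% and 1.09% (odds ratio 1.36, Fisher adjusted p = 0.208 over 10 classes). For rRNA genes there was 1 such peak, on the mitochondrial genome (odds ratio 7.20, 0.16 to 56.1, Fisher adjusted p = 0.208). A further 2 nuclear regions near 5S rRNA genes passed the reproducibility threshold but are outside the thresholded list, so they are not counted here. Of the 612 nuclear tRNA genes, 261 (42.6%) had a summit within 300 bp, as did 78 of 346 snoRNA genes and 29 of 129 snRNA genes. For tRNA, snoRNA, snRNA and rRNA genes together the share was 23.6% of pooled peaks against 0.773% (odds ratio 39.6, 34.2 to 45.7, and 66.58 at a global irreproducible discovery rate of 0.001 or less). It was 26.4% in replicate 1's own list (p = 5.0e-188) and 33.1% in replicate 2's (p = 1.0e-182, both Fisher's exact test, two-sided). This grouping was chosen after the peaks had been seen. Near-identical tRNA gene copies can share reads, so the peak at a single copy is uncertain.

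**Figure D1:**
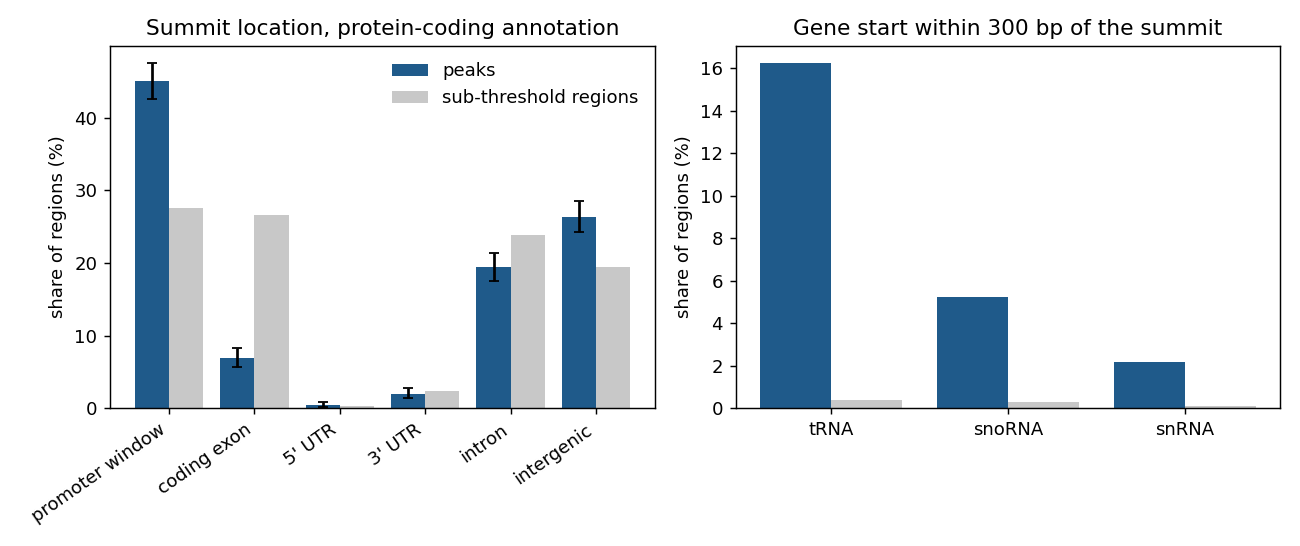
The left panel plots the share of regions (%) by summit location for peaks (blue, with 95% Wilson intervals) and sub-threshold regions (grey), and the right panel the share with a tRNA, snoRNA or snRNA gene start within 300 bp. Promoter windows hold 45.01% of peaks against 27.6%, and tRNA gene starts lie at 16.23% against 0.392%.

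Peaks were spread over all chromosomes, with more on X and fewer on II and V than among weaker regions. Chromosome X held 323 of 1537 nuclear peaks (21.02%) against 17.7% of weaker regions (odds ratio 1.23, 1.09 to 1.40, Fisher's exact test, two-sided, p = 0.00122). Chromosome V held 17.05% against 20.4% (odds ratio 0.80, Fisher adjusted p = 0.00366 over 6 chromosomes) and chromosome II 14.4% against 16.7% (odds ratio 0.84, adjusted p = 0.0339). X also carried 45.1% of tRNA genes, and without peaks and weaker regions at small non-coding RNA genes its odds ratio was 0.977 (Fisher p = 0.788), which ended the call and turned its direction. Autosome arms, the outer 30% at each end, held 51.7% of autosomal peaks and 62.1% of weaker regions (odds ratio 0.655, 0.583 to 0.735, Fisher p = 4.4e-13).

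Promoter peaks had a slightly higher signal than other peaks. Nuclear peaks at tRNA, snoRNA, snRNA or rRNA genes had a median signal of 93.8 and other nuclear peaks 78.3 (permutation test, two-sided, p = 1e-05, the smallest it can give). That class was chosen after its genes had been seen among the strongest peaks, so the test partly restates that choice. Promoter peaks had a median signal of 83.1 and other peaks 78.8 (permutation test, two-sided, p = 0.0069). The difference was 2.18 in the conservative list (permutation p = 0.206), 2.59 with only replicate 2's list (permutation p = 0.223) and 1.65 with only replicate 1's list (permutation p = 0.205). Narrower and wider promoter windows also ended the call (differences of 3.21 and 2.23). Without peaks at small non-coding RNA genes the difference was 6.39 (permutation p = 5e-05). Signal levels differed between the pooled list (median 81.1) and the lists of replicate 1 (60.9) and replicate 2 (52.3). Differences from the replicates' lists are therefore not comparable in size with the pooled one.

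The genes under EGL-44 promoter peaks were tested in 21 lists fixed before the data were examined. In all, 805 of 19973 nuclear protein-coding genes (4.03%) had a promoter peak. By Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment, 4 lists held more such genes than the rest of the genome and 1 held fewer.

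Of 12 EGL-44 partner and Hippo pathway genes, 4 had a promoter peak (33.3%, odds ratio 11.96, 95% interval 2.63 to 44.7, Fisher adjusted p = 0.0042). They were par-5 (14-3-3 protein; IV:11821983-11822292, signal 145.1), nfm-1 (the merlin homologue; III:6158670-6158979, 109.02), egl-44 itself (II:5936009-5936318, 99.5) and wts-1 (the LATS kinase of the Hippo pathway; I:10297893-10298202, 94.4). The egl-44 peak lay within the gene, 277 bp upstream of an annotated transcript start, and was in replicate 1's own list but not in replicate 2's. The nfm-1 peak also lay within 300 bp of a small non-coding RNA gene, and the wts-1 peak was in neither replicate's own list. When each summit was given only to its nearest gene, coding or non-coding, the odds ratio was 3.91 and the call was lost (Fisher adjusted p = 0.633). The odds ratio was 18.2 in the conservative list and 19.1 at an irreproducible discovery rate of 0.001 or less.

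Cytosolic ribosomal protein genes held 23 members with a promoter peak among 78 (29.5%, odds ratio 10.2, 5.96 to 17.01, Fisher adjusted p = 2.7e-13). The strongest were rpl-3, rpl-35, rpl-15 (IV:654856-654990, signal 267.97) and rpl-18A (IV:4749998-4750143, 255.3), and all 4 were in both replicates' own lists. Histone genes held 14 of 72 (19.4%, odds ratio 5.83, 2.99 to 10.6, Fisher adjusted p = 6.3e-06), on 12 distinct peaks. They included his-37 (V:9546941-9547054, 199.02), his-59 (136.1), his-56 (116.6) and his-48 (94.1). Histone genes have near-identical copies, so their assignment is uncertain, and with the narrower promoter window the odds ratio was 2.55 (Fisher adjusted p = 0.165). Against only genes with any ranked region it was 8.79. Stress response and longevity genes held 8 of 40 (odds ratio 6.0, 2.38 to 13.4, Fisher adjusted p = 8.6e-04). Their strongest members were the chaperone genes hsp-60 (159.4), hsp-3 (153.4) and hsp-90 (104.2) and hlh-30 (149.1), the TFEB homologue that drives autophagy genes. The other members with a promoter peak, named here beyond the rule, were xbp-1, hsp-110, hsp-1 and atfs-1. Listed genes such as daf-2, daf-16, age-1, akt-1, skn-1 and sod-3 had none. The call therefore does not extend to every part of this list. With the nearest gene only, coding or non-coding, the stress list's odds ratio was 4.81 (Fisher adjusted p = 0.0663). It was 9.71 in replicate 2's own list and 12.26 at an irreproducible discovery rate of 0.001 or less.

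Chemoreceptor genes were depleted, with a promoter peak at 8 of 1275 (0.627%, odds ratio 0.142, 0.0609 to 0.282, Fisher adjusted p = 2.7e-13). Of their 4 strongest, sre-23 (236.4), srh-269 (155.4), srh-2 (135.7) and sri-5 (99.1), the first pair also lay within 300 bp of a small non-coding RNA gene. The chemoreceptor odds ratio was 0.0938 in the conservative list, 0.0818 without peaks at small non-coding RNA genes and 0.24 among genes with any ranked region.

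The remaining 16 lists did not pass the threshold. The actin cytoskeleton and adhesion list held 4 of 32, spc-1 (132.1), ajm-1 (130.03), wve-1 (95.6) and zyx-1 (64.9), with an odds ratio of 3.41 (Fisher adjusted p = 0.135). This group passed in replicate 2's own list alone, with an odds ratio of 6.99, and had 2.86 in replicate 1's own list. Cuticle collagen genes held 2 of 176, col-185 (108.8) and col-52 (46.5), with an odds ratio of 0.272 (0.0326 to 1.0, Fisher adjusted p = 0.154). Neuropeptide genes held 2 of 147, ins-39 (123.02) and nlp-76 (64.3, Fisher adjusted p = 0.354), and intestine genes 2 of 30, elt-2 (68.5) and fat-6 (55.6, adjusted p = 0.799). Of 15 touch receptor neuron genes only mec-6 (78.9) had a promoter peak (odds ratio 1.70, 0.0402 to 11.2, Fisher adjusted p = 0.891). The mec-6 peak was in neither replicate's own list, and each of these held 0 of the 15 genes. A single member had a promoter peak in each of the cell cycle (lin-23, 80.99), body wall muscle (unc-112, 60.3), pharynx (pha-4, 63.4), epidermal and seam cell regulator (nhr-49, 76.8), germline (pgl-3, 84.01), pan-neuronal (unc-108, 80.8) and vulva, uterus and gonadal sheath (egl-17, 133.2) lists. No member had a promoter peak among 26 basement membrane, 28 Wnt and Hox, 31 major sperm protein and 5 heterochronic microRNA genes. Cuticle collagen genes passed with the narrower window (0 of 176, Fisher adjusted p = 0.0451) and neuropeptide genes with the wider window (Fisher adjusted p = 0.0445). The peaks at ajm-1, col-185 and egl-17 also lay within 300 bp of a small non-coding RNA gene.

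**Figure D2:**
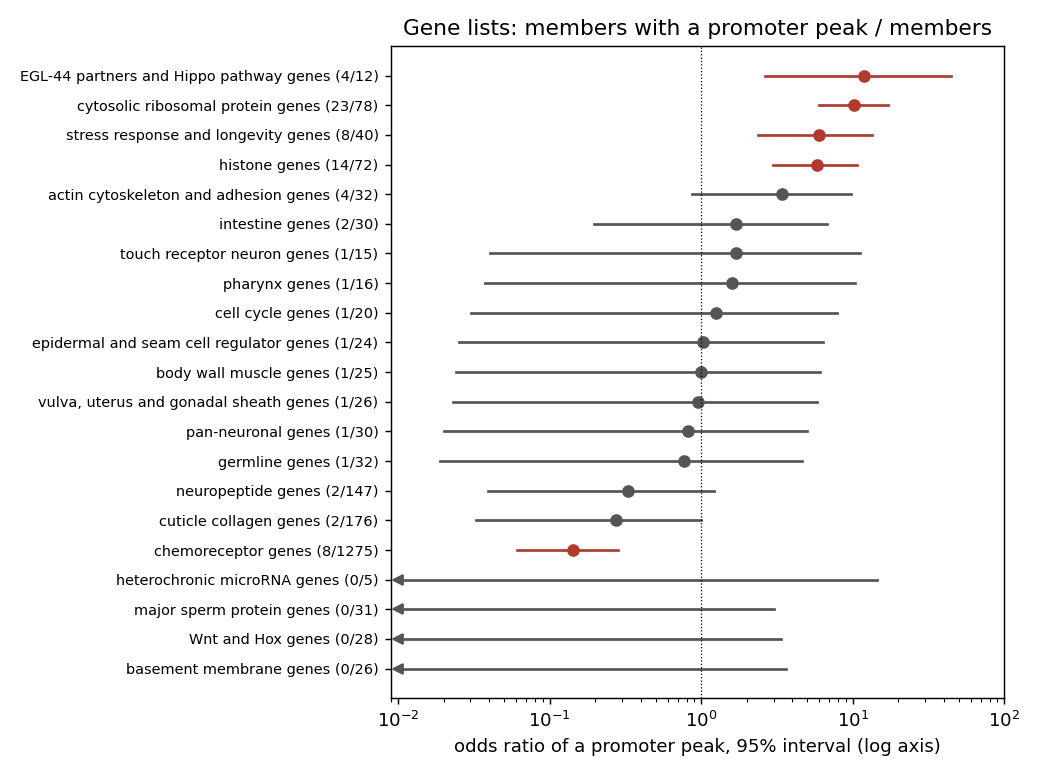
Points give the odds ratio of a promoter peak for each list (log axis) with 95% intervals, and list members with a peak over all members stand in brackets. Red marks an adjusted p under 0.05, and arrowheads at the left edge mark lists in which 0 members had a promoter peak. The EGL-44 partner (11.96), ribosomal protein (10.2), stress (6.0) and histone (5.83) lists lie above 1 and the chemoreceptor list (0.142) below it.

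Genes tied to EGL-44 by earlier genetics mostly lacked a promoter peak. The cyclin E gene cye-1, which EGL-44 is known to repress in some neuronal precursors, had a peak in an intron at I:6781660-6781969, 1009 bp downstream of its start, with signal 130.1 and in both replicates' own lists. That peak also lay within 300 bp of a small non-coding RNA gene, so its assignment to cye-1 is uncertain. For mec-3, the homeodomain regulator of touch receptor fate, the nearest peak was 1451 bp upstream of the start (IV:10463163-10463472, 62.2), outside the promoter window. It lay inside the wider window of 2000 bp up. With that window the touch receptor list held 2 of 15 (odds ratio 2.48, 0.271 to 11.0, Fisher adjusted p = 0.494). The nearest peaks to yap-1, egl-46 and unc-86 were 4438, 22492 and 11337 bp away. For mec-4, mec-7, mec-17 and mec-18 the nearest summits were 14883, 46593, 22500 and 51268 bp from the start, and for zag-1 133009 bp. Weaker regions lay in the promoter windows of mec-3 (3), mec-7 (2), mec-17 (3), mec-18 (2), egl-46 (1), yap-1 (2), cye-1 (1) and zag-1 (1). The windows of mec-4 and unc-86 held none. Such regions are common, since 12742 of the 19973 nuclear protein-coding genes had a ranked region, peak or weaker, in the promoter window. These counts are therefore no sign of binding at the named genes. In whole worms, a site used in a few neurons can be diluted by the other cells.

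The TEAD core word CATTCC was not enriched at EGL-44 summits. It lay within 100 bp of 133 of 1553 summits (8.56%, 7.27 to 10.1) and of 11.2% of 7765 weaker regions matched on promoter status and GC content (odds ratio 0.745, 0.611 to 0.904, Fisher's exact test, two-sided, p = 0.00224). The windows 500 bp to either side of the same summits held it in 9.11% (odds ratio 0.934, 0.747 to 1.16, Fisher p = 0.549). The shortfall was thus called against the weaker regions, which held the word more often than these flanks, but not against the flanks. Among the 60 words made of the same bases, CATTCC ranked 45 by odds ratio, and ACTCTC ranked 1 (1.69). Differences were common in this comparison: of all 2080 words of 6 bases, 416 were enriched and 376 depleted. In replicate 2's own list the odds ratio was 0.785 (Fisher p = 0.142), and with 50 bp windows it was 0.809 (p = 0.115), so the shortfall was not called there. From the weakest to the strongest signal quintile, 10.9%, 7.72%, 8.06%, 6.75% and 9.35% of peaks held the word (correlation with quintile -0.0209, permutation test, two-sided, p = 0.422). With a global irreproducible discovery rate of 0.001 or less the correlation was 0.0995 (permutation p = 0.0143), of the opposite sign.

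**Figure D3:**
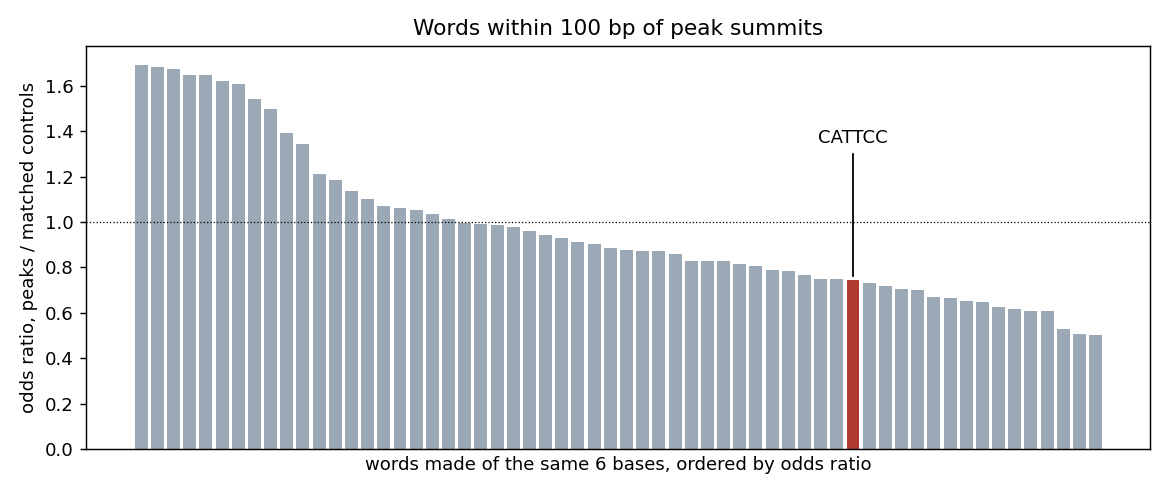
Bars give the odds ratio of each of the 60 words made of the bases of CATTCC, peaks over matched sub-threshold regions, within 100 bp of the summit. The dotted line marks 1, and CATTCC (red) lies below it at 0.745.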

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

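Regions that passed the reproducibility threshold but are outside the thresholded lists are described here, because the comparisons leave them unused. There were 23 such regions for the pooled list. The strongest, at X:15810954-15811263, had a signal of 1056, above every nuclear peak in the list, and its nearest annotated start was that of the pseudogene Y7A5A.11. The next, at IV:14779933-14780242 (308.9), was near the ncRNA gene Y57G11C.1141, and 2 lay near 5S rRNA genes, rrn-4.11 (111.3) and rrn-4.7 (95.8). The labels name 1 more source for the thresholded lists than for the ranked lists, and its content was not used here. Why these regions are outside the list is not given in the sources used here, and no explanation was tested.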

How the results depend on the processing

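The settings named here as added were chosen after seeing the data. They were an IDR limit of 0.001, and leaving out mitochondrial regions, regions of low signal, or peaks at small non-coding RNA genes. For the small non-coding RNA share, a gene start within 100 bp was also added (odds ratio 56.8). The planned IDR limit of 0.01 moved nothing, because the lists already stop there. Leaving out mitochondrial regions could not change the nuclear gene lists, the arm share or the X share. Both settings are included in the counts of settings given next. The promoter share (10 settings), the arm share (9), the small non-coding RNA share (8) and the odds ratios of the ribosomal protein and chemoreceptor lists (12 each) kept their direction and call in all of these. The X share kept both in 7 settings and turned to 0.977 without small non-coding RNA peaks, where X carries 45.1% of tRNA genes. The promoter difference in signal kept its sign but not its call at 2.18 (conservative list) and 0.625 (IDR 0.001). The same held at 3.21 (500 bp up, 100 bp down) and 2.23 (2000 bp up, 500 bp down). With 1 replicate left out it ranged from 1.65 to 2.59, also without a call, on lists of lower signal. Those sizes are not comparable with the others. The word's odds ratio stayed below 1 but was not called at 0.809 (50 bp windows), 0.872 (longer word RCATTCCW) or 0.785 without replicate 1 (0.722 without replicate 2). The word trend turned to 0.0995 at an IDR of 0.001, ran from 0.0403 to 0.0785 with 1 replicate left out, and passed the threshold at -0.0539 (250 bp windows). Enriched lists numbered 4 as planned and 2 with the nearest gene only. That setting removes a gene wherever another start, coding or non-coding, is nearer the same summit. The number was 3 with the narrower window (histone lost) and 5 without replicate 1 (actin added). Depleted lists numbered 1, and 2 with the narrower window, which added cuticle collagen, and 2 with the wider window, which added neuropeptides. The overlap of replicate 2 with replicate 1 was 55.3% between ranked lists, and rho over all ranked regions was 0.273. Except where a reason is given, the cause was not tested. Leaving out a replicate gives no value for replicate overlap, rank agreement or nesting. No paired analysis was possible because there is 1 group. Depth is unknown, so what depth limits could not be measured.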

Other observations

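The gene-name families, the sequence words and the low-signal regions below were looked at only after the data had been seen. The tests of explanations further down were also chosen after the patterns, the shares by RNA class and the unmatched word shares had been seen, with their predictions written before each test was run. Among 180 families of at least 10 nuclear protein-coding genes that share a name prefix, 8 had more promoter peaks than other genes (Fisher's exact test, two-sided, Benjamini-Hochberg). Besides the rpl, rps, his and hsp families these were the cox family of cytochrome oxidase subunits (5 of 15, odds ratio 11.97, Fisher adjusted p = 0.0101), the vha family of vacuolar ATPase subunits (5 of 20, 7.98, adjusted p = 0.0197), the dnj family of DnaJ chaperones (6 of 29, 6.25, adjusted p = 0.0197) and lin genes (8 of 47, 4.92, adjusted p = 0.0157). The cox members were cox-4, cox-5A, cox-5B, cox-6A and cox-6B. The name rule was widened to letter suffixes after a first output had been seen, and 4 of these 5 carry a suffix, so the cox call rests on that change. The chemoreceptor family str had 0 of 193 (Fisher adjusted p = 0.0168). A minimum of 8 members, used in an earlier run, added hmg (4 of 9, odds ratio 19.1, Fisher adjusted p = 0.0124).

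Many sequence words differed from matched controls: 416 of 2080 were enriched and 376 depleted over all peaks, and 274 and 316 with mitochondrial and small non-coding RNA peaks left out. No word named here is therefore specific by its p alone. Of these words of 6 bases, each counted with its reverse complement, CGAACC had the lowest p over all peaks (16.098% of summits against 6.0% of matched controls, odds ratio 3.01, Fisher adjusted p = 4.3e-32). With mitochondrial peaks and peaks at small non-coding RNA genes left out, GAGAGA (31.7% against 16.3%, odds ratio 2.38, Fisher adjusted p = 3.9e-28) and ACGCAG (19.05% against 7.47%, 2.92, adjusted p = 6.6e-27) led, and CATTCC had an odds ratio of 0.828 (adjusted p = 0.218). The count over all peaks used the controls of the CATTCC test, and the count without these peaks a new draw from all weaker regions.

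A total of 77 pooled peaks had a signal below the median of the weaker regions, 20.8. Of these, 76 (98.7%) had a stronger ranked region within 310 bp. The other peaks are no comparison for this, since the groups were split by signal.

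The excess of small non-coding RNA genes at peaks was weighed against 4 technical explanations. If GC content produced it, GC-matched controls would remove it, but against GC-matched weaker regions the odds ratio was 31.6 (24.4 to 41.4). It did not come from a single library, since the smaller of the replicates' own odds ratios was 28.5 (23.7 to 34.1). Reads shared between identical tRNA gene copies would spare single-copy genes. Yet 35.7% (28.3 to 43.9) of the 140 tRNA genes whose sequence occurs once had a summit within 300 bp, against 2.25% of protein-coding genes. The share was 44.7% (40.3 to 49.2) for the 472 tRNA genes whose sequence occurs more than once. A partial contribution of shared reads is thus left open, and near-identical copies were not excluded. Uneven pull-down of all heavily transcribed genes stays open: the prediction was an odds ratio above 1 in 3 lists of abundant transcripts, and it was not met, with 10.2 for ribosomal protein, 1.70 for intestine and 0.992 for body wall muscle genes. The lowest upper bound was 6.1, so these lists do not exclude it either. The untagged or input control that would test it was not used here. Whether uneven pull-down also raised the gene lists called enriched was not tested. The body wall muscle value rests on 1 of 25 genes. The intestine value rests on elt-2 and fat-6, whose peaks were in neither replicate's own list. Each of those lists held 0 of 30 intestine genes.

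The lack of CATTCC at summits was weighed in the same way. The controls were weaker regions of the same ChIP. Whether these hold EGL-44 sites with the word was not tested, so the checks do not cover that. Dilution by small non-coding RNA peaks would hide an enrichment elsewhere, but without those peaks the odds ratio was 0.78 (0.624 to 0.968). With mitochondrial peaks also left out and controls from all weaker regions it was 0.828 and not called; which of these choices moved it was not tested. If GC content masked an enrichment, matching would raise the odds ratio, but it was 0.788 with unmatched controls and 0.745 (0.611 to 0.904) with GC and promoter status matched; the latter is the value that defines the pattern, so it is no separate test. If only the strongest peaks held the word, the top signal quintile would show it, but its odds ratio was 0.922 (0.586 to 1.41), an interval that leaves room for a small excess. A candidate explanation left open is that many peaks reflect chromatin recovered without direct TEAD binding, which these files do not test; no biological explanation was tested.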
